A study of Homo sapiens with 8 samples.

How the data were processed

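RNA of 4 control and 4 ethanol-treated cultures of the esophageal squamous line KYSE510 was profiled, each labelled with Cy3 and hybridised to its own Agilent array, per the labels. The labels describe the samples as biological replicates of each group. They also give an extraction protocol for mouse esophageal tissue, while the organism, the cell line and the array design are human, and the samples were treated as human cells. RNA was amplified and labelled with an Agilent linear amplification kit for low RNA input, per the labels' protocols; such kits prime on the poly(A) tail. Scanner values are spot intensities that the authors deposited as Feature Extraction output, background-subtracted and spatially detrended on each array and not scaled between arrays, per the file headers. The headers name Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. Probe positions refer to the hg19 build, per the file headers. The authors also deposited a table of log2 values of the same arrays. Set against the scanner values over probes above background on all arrays, its differences between arrays had a slope of 1 and a correlation of 1. Its scale is thus log2, and every probe is centred on its median over the 8 arrays. The medians of its columns were 0.036, −0.017, −0.015 and −0.037 for control replicates 1 to 4 and 0.145, 0.031, −0.014 and −0.038 for ethanol replicates 1 to 4. It was used as an alternative, and no column of it was left unused.

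Each array held 62976 spots, of which 58717 were not controls and represented 50599 probes. No such spot was saturated, and no pair of arrays held identical values. Control spots and spots flagged as non-uniform or as population outliers were left out, between 217 and 423 flagged spots per array. The log2 of the processed signal was averaged over spots of a probe, and the 75th percentile of each array's non-control probes was subtracted. A probe was kept when it was well above background on at least 4 of the 8 arrays, which left 29349 probes. Names were updated through the RefSeq gene table of GRCh38.p14, from which no coordinate is given. Of the 50599 probes, 29033 were named through their accession, 30 through another accession, 2958 through a current symbol and 571 through an older symbol. For 122 the file's own name was kept, and 17885 stayed without a gene symbol. Of the kept probes, 23101 had a gene and 6248 had none. The probe with the highest mean over the 8 arrays stood for each of 16270 genes. Of 1869 changed genes with more than 1 kept probe, 111 had another probe that passed in the opposite direction.

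Ethanol was compared with control by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with group as the single term and the adjusted p of Benjamini and Hochberg over all genes under 0.05. Log2 changes are ethanol minus control, with the standard error of the fit. Where no array of a group was well above background, a change is given as a bound. The brighter group's mean was set against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. This applied to 29 of the changed genes. The 36 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over 35 lists with at least 5 tested members. These tests used the 16240 genes without missing values. List medians and counts cover those genes. For a test of the code, changes were added to simulated values of 16240 genes in the ethanol against control design. It recovered 78 of 100 genes changed 1.5-fold and 94 of 100 changed 2-fold, with 8 false calls. The share of genes changed there was far below the 38.0% called in the data. The adjusted p depends on that share, so these counts test the code and do not give the error rates of the real comparison. A simulated list of 30 genes shifted by 0.3 was called, and 0 of 20 unshifted lists were. The simulated genes varied independently of each other, so the preset correlation itself was not put to a test.

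The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, passing over placeholder symbols. It added up to 4 members of each list with the smallest p, and 21 genes of ethanol metabolism, stress and squamous identity whatever their p. The alternatives were the replicate number as a block, a normexp background correction (offset 50), quantile normalization, scaling on the median or on the 75th percentile over probes above background on all arrays, no filter or a stricter filter on dim probes, the mean of a gene's probes, a trended and robust variance, array weights, the deposited table, and each replicate left out. Scaling on 8 spike-in controls and removal of each array's trend with probe GC content were added after the data were seen. A few genes that the rule takes are not reported here. Some list members were not named on the array here and were not analysed. The number of arrays, 4 per group, limits the precision, with a median standard error of 0.067 on the log2 scale over genes.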

Results

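Gene expression was measured in KYSE510 cells, an established line from a human esophageal squamous cell carcinoma, after 72 h with 100 mM ethanol and in untreated control cultures. Each group had 4 biological replicates, and each replicate was hybridised to its own one-colour array. The comparison asks which transcripts ethanol raised or lowered in this squamous epithelial line. The 75th percentile of the signal lay between 1414 and 1587 units on the control arrays. It was 934 units in ethanol replicate 1 and 1488 to 1670 units in the other 3 ethanol replicates. Between 55.1% (ethanol replicate 1) and 60.4% (control replicate 3) of 50599 probes were well above background, and 16270 genes were tested. All 8 arrays lay on 1 slide, the controls in row 1 and the ethanol cultures in row 2, so that slide row and treatment cannot be told apart.

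The transcript that rose most with ethanol was UBD, which encodes a ubiquitin-like modifier induced by inflammatory cytokines. It was 7.43-fold higher (log2 change 2.89 ± 0.07, SE, n = 4 per group, limma adjusted p = 4.83e-07). The cholesterol exporters ABCG1 and ABCA1 rose 4.51-fold (log2 change 2.17 ± 0.06) and 4.24-fold (2.08 ± 0.06). NLRP7, a member of the NOD-like receptor family, rose 4.65-fold, the cytokine IL6 3.89-fold and the chemokine CCL5 3.75-fold. GALNT14, a glycosyltransferase, was not well above background on any control array and was at least 2.21-fold higher with ethanol. Dimmer probes of CXCL11, an interferon-induced chemokine, FAM106A and KIAA0408 completed the 10 largest rises, with fitted log2 changes of 1.94 ± 0.44, 2.13 ± 0.59 and 2.05 ± 0.50. In these 3 genes, 1, 1 and 2 of the 4 control arrays were well above background.

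Among the genes that fell, the largest fitted change was in PSG5, a pregnancy-specific glycoprotein that was well above background on only 1 of the 4 ethanol arrays, so that its fold and its rank depend on background (5.89-fold, log2 change −2.56 ± 0.35, SE, n = 4 per group, limma adjusted p = 0.00107). The calcium-binding protein gene CALB1 was 5.74-fold lower, and ANGPTL4, a secreted inhibitor of lipoprotein lipase that is induced by hypoxia and PPAR ligands, was 4.90-fold lower. GDF15, a stress-induced cytokine, fell 4.04-fold (log2 change −2.01 ± 0.09), and COXFA4L2, known under the older symbol NDUFA4L2 as a hypoxia-induced mitochondrial protein, fell 3.92-fold. The histone gene H2AC19 fell 3.85-fold (log2 change −1.95 ± 0.04) and the noncoding transcript LINC00520 4.57-fold. KCTD4, LINC02582 and CFAP100-DT were not well above background on any ethanol array and were at least 1.30-fold, 1.70-fold and 1.56-fold lower. With ethanol, CALB1 was well above background on 2 of the 4 arrays and LINC00520 on 3. PSG5, FAM106A and H2AC19 have near-identical relatives that can share a probe's signal.

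**Figure D1:**
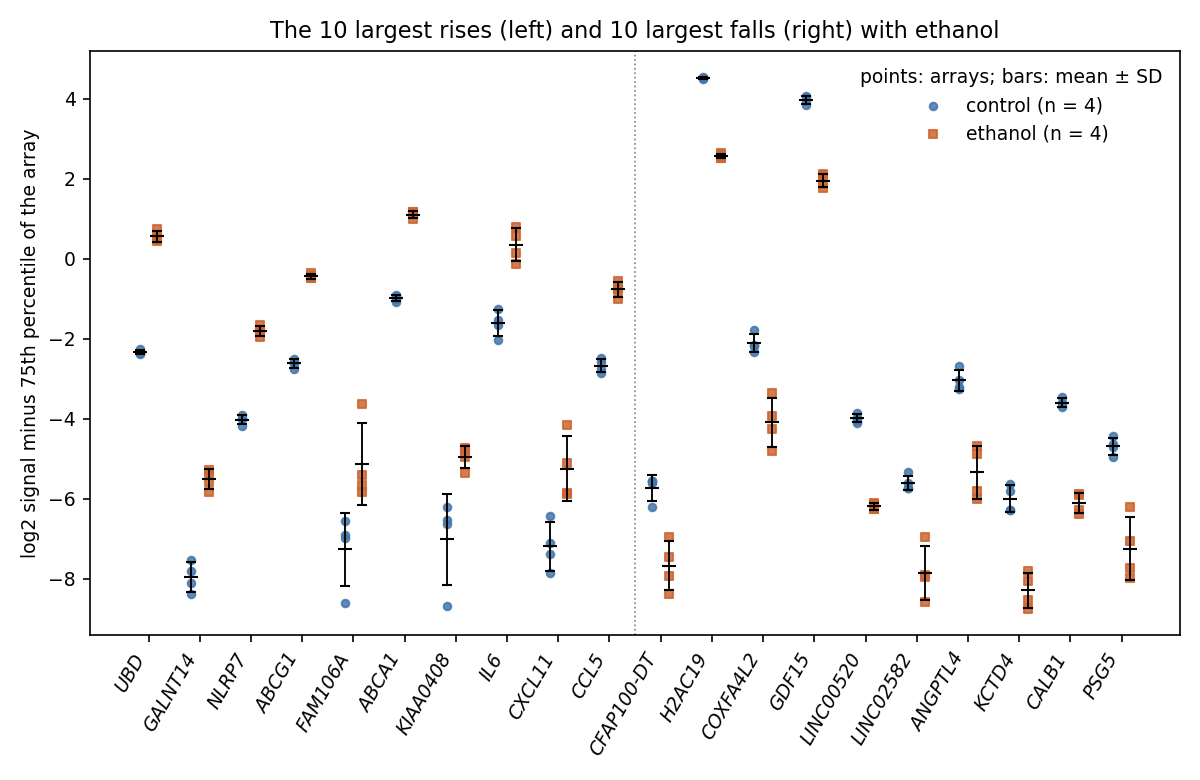
Per-array values of the 10 genes that rose most and the 10 that fell most, as log2 signal minus the array's 75th percentile. Circles are the 4 control arrays, squares the 4 ethanol arrays, and bars the mean ± SD. All 20 genes were taken among genes that passed and whose groups do not overlap, so the lack of overlap follows from the choice. Log2 changes were 2.89 for UBD, 1.91 for CCL5 and −1.95 for H2AC19.

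On the array's genome build (hg19), the probe of UBD lies on chromosome 6 at positions 29523477 to 29523536. The probe of ABCA1 lies on chromosome 9 at 107543704 to 107543763, and that of ABCG1 on chromosome 21 at 43716784 to 43716843. IL6 was read on chromosome 7 at 22771207 to 22771266 and CCL5 on chromosome 17 at 34199332 to 34199391. Of the genes that fell, GDF15 was read on chromosome 19 at 18499890 to 18499949, PSG5 on chromosome 19 at 43674208 to 43674267 and CALB1 on chromosome 8 at 91071700 to 91071759. Each probe is paired with a transcript of its gene in the files.

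In all, 6187 of the 16270 genes changed at a limma adjusted p under 0.05, or 38.0%, with 2495 higher and 3692 lower with ethanol. At least 1.5-fold changes were seen in 1074 of them (551 higher, 523 lower), and at least 2-fold changes in 266 (128 higher, 138 lower). In 38.4% of all tested genes the 4 ethanol values all lay above or all below the 4 control values, which chance gives for 2.86% of genes. The share of higher genes among the changed ones was 40.3% but moved with the scaling. It was 20.8% after median scaling, 48.9% after quantile normalization, 57.3% when the 75th percentile was taken over probes above background on all arrays, and 71.6% with spike-in scaling, an alternative added after the data were seen. Median scaling also lowered the median log2 change of all genes from −0.04 to −0.14, and spike-in scaling raised it to 0.07. With a normexp background correction, 545 genes changed at least 1.5-fold. The changes of dim genes shrank most there, to −0.56 in PSG5, −0.94 in CALB1, −0.81 in LINC00520, −1.21 in ANGPTL4, −1.37 in COXFA4L2, 0.63 in CXCL11, 0.62 in KIAA0408 and 0.51 in GALNT14. Among genes named below, FABP4 shrank to −0.42, DCN to −0.66, MMP2 to 0.64, TNF to 0.56, ACADS to −0.36 and ABCG2 to −0.21. The calls of KCTD4 (−0.23), CFAP100-DT (−0.32), LINC02582 (−0.35) and FAM106A (0.61) ended. With the mean of a gene's probes, LFNG shrank from 0.71 to 0.34, ACSS1 from 0.42 to 0.22, CRABP2 from −0.67 to −0.36 and HRK from −0.58 to −0.38, and TNFSF10 grew from 0.40 to 0.68. In LFNG, SREBF1 and VWF, 1 of 2 kept probes had the sign that is given, and in AKR1C1 2 of 3. Of genes named below that did not pass, this was 1 of 2 in ALDH1A1 and 1 of 3 in MKI67.

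**Figure D2:**
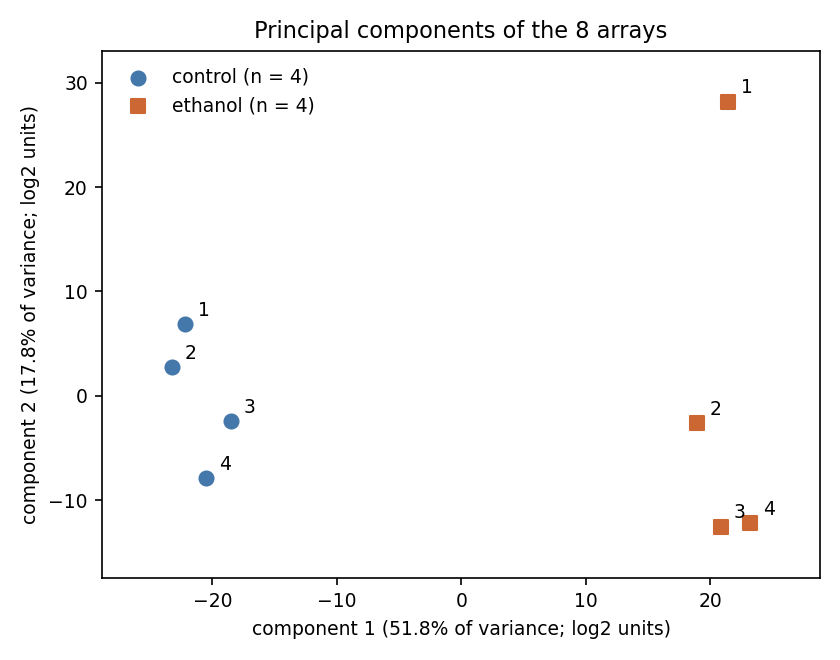
First 2 principal components of the 8 arrays over genes, with control arrays as circles and ethanol arrays as squares, numbered by replicate. Component 1 (51.8% of the variance) separates the groups, and component 2 (17.8%) places ethanol replicate 1 at 28.2, against −2.62 to −12.6 for the other ethanol arrays.

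Of 36 gene lists fixed before the data were examined, 35 had at least 5 tested members, and 10 of these shifted relative to all other genes by camera with a preset correlation. With the correlation estimated from these arrays, none of the 35 lists passed. The smallest adjusted p was then 0.0875, and the number of arrays limits that estimate. At an adjusted p under 0.05, fry called 25 lists. It asks whether a list changed at all, not whether it changed relative to other genes, so this count answers another question. Camera and adjusted p-values below are from limma, and medians are log2 changes, ethanol minus control. The medians of the 10 shifted lists kept their sign under each of the 21 alternative settings, but their size moved with the scaling. With median scaling, the medians were 0.03 for WNT targets, 0.04 for interferon-stimulated genes, 0.04 for heat shock genes and 0.07 for NF-kB and inflammatory mediators. With spike-in scaling, they were −0.04 for oxidative phosphorylation, −0.08 for NRF2 targets, −0.12 for G2 and mitosis and −0.13 for glycolysis and hypoxia. With spike-in scaling, the calls of 53 of the 148 named genes that changed ended. Beside those noted further below, they were the calls of ABCG2, AHCY, AHCYL1, ALDH3B1, ALDOC, CDCA7, CDKN1B, CLDN1, DDB2, DHRS3, DNAJB1, DSG3, ESRP1, FABP5, FANCC, FANCE, GPX2, GSTA4, HERPUD1, HES2, HMOX1, KLF9, KRT5, NQO1, NRARP, PHLDA1, PKP3, RAD54L, S100A4, SOX2, UVRAG and XBP1.

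Genes of the integrated stress response, which ATF4 turns on when amino acids run short or the endoplasmic reticulum is stressed, were lower with ethanol. Of 27 tested members, 22 fell, 1 rose and 4 did not pass (23 fell and 2 rose adjusted over the list alone). The median was −0.42, and camera gave an adjusted p = 1.39e-08, or adjusted p = 0.0875 with an estimated correlation. Asparagine synthetase (ASNS) fell 2.03-fold (−1.02 ± 0.04), the secreted hormone STC2 2.58-fold (−1.37 ± 0.07), and CTH and PSAT1, enzymes of cysteine and serine synthesis, 1.68-fold and 1.63-fold. DDIT3, which encodes the transcription factor CHOP, fell by 0.38 ± 0.12 on the log2 scale, a call that was lost under 11 of 21 alternatives, whose adjusted p reached 0.166.

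Replication-dependent histones fell in 23 of 32 tested members, none rose, and 9 did not pass (25 fell adjusted over the list alone; median −0.51, camera adjusted p = 3.24e-09, adjusted p = 0.43 with an estimated correlation). H2AC17 fell 1.96-fold, H2BC11 1.78-fold, H2BC18 1.73-fold and H2BC3 1.69-fold. Most transcripts of these genes lack the poly(A) tail on which such labelling kits prime, and their sequences are similar enough to share probes. Genes of G2 and mitosis fell in 33 of 44 members and rose in none, with 11 not passing (36 fell adjusted over the list alone). Their median was −0.23 (camera adjusted p = 8.61e-08, adjusted p = 0.43 with an estimated correlation). The centromere chaperone HJURP (−0.38 ± 0.05), the spindle genes HMMR (−0.44 ± 0.04) and KIF2C (−0.34 ± 0.04), and the kinetochore gene NUF2 (−0.37 ± 0.04) were among them, though the calls of all 4 ended with spike-in scaling. Genes of the G1/S transition did not shift as a list (4 higher and 11 lower of 40, also adjusted over the list alone; median −0.06, adjusted p = 0.477). The cyclins CCNE2 (0.51) and CCNE1 (0.47) rose there, while CDCA7 (−0.40) fell. The proliferation marker MKI67 had a log2 change of 0.13 ± 0.16 that did not pass (adjusted p = 0.577), and only 1 of its 3 kept probes had that sign.

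Glycolysis and hypoxia genes fell in 15 of 28 members and rose in none, with the same counts adjusted over the list alone (median −0.24, camera adjusted p = 0.000633, adjusted p = 0.528 with an estimated correlation). The vasodilator peptide gene ADM fell 2.17-fold, hexokinase HK2 1.81-fold, PFKFB3, which drives glycolytic flux, 1.61-fold, and the aldolase ALDOC 1.41-fold. The call of HK2 was lost with the mean of its probes (−0.50, adjusted p = 0.295). Subunits of oxidative phosphorylation complexes I to V fell in 24 of 50 members and rose in none (26 fell adjusted over the list alone). Their median was −0.15 (camera adjusted p = 2.45e-05, adjusted p = 0.43 with an estimated correlation). NDUFS7 of complex I (−0.43 ± 0.04), the ATP synthase subunits ATP5F1D (−0.35) and ATP5MC1 (−0.32), and COX8A of complex IV (−0.34) fell, calls that all ended with spike-in scaling. Targets of NRF2, the regulator of the oxidant response, fell in 18 of 30 members and rose in 2, unchanged adjusted over the list alone (median −0.19, camera adjusted p = 0.00453, adjusted p = 0.43 with an estimated correlation). The aldo-keto reductases AKR1B10 and AKR1C1 fell 1.77-fold and 1.63-fold and the glutathione peroxidase GPX2 1.32-fold, whereas the efflux transporter ABCC3 rose 1.91-fold. The NRF2 targets NQO1 (−0.36 ± 0.06) and HMOX1 (−0.44 ± 0.06) also fell.

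Interferon-stimulated genes were higher with ethanol, with 21 of 46 members up, 3 down and 22 not passing (22 up and 3 down adjusted over the list alone). The median was 0.14 (camera adjusted p = 2.45e-05, adjusted p = 0.43 with an estimated correlation). The nucleotide kinase CMPK2 rose 3.08-fold, OASL 2.15-fold, the double-stranded RNA sensor OAS1 1.51-fold and the immunoproteasome subunit PSMB9 1.32-fold. NF-kB and inflammatory mediators rose in 9 and fell in 5 of 32 members (9 and 7 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.0135, adjusted p = 0.483 with an estimated correlation). Beside CCL5, the acute-phase gene SAA1 rose 2.21-fold, TNF 1.81-fold and the mitochondrial superoxide dismutase SOD2 1.27-fold. Heat shock genes rose in 7 and fell in 3 of 20 members (8 and 3 adjusted over the list alone; median 0.14, camera adjusted p = 0.0235, adjusted p = 0.43 with an estimated correlation). CRYAB (1.70-fold), HSPA4L (1.56-fold) and HSPH1 (1.30-fold) rose, while the co-chaperone DNAJB1 fell by 0.26 on the log2 scale. WNT pathway targets rose in 5 and fell in 2 of 15 members, with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.0119, adjusted p = 0.43 with an estimated correlation). DKK3 (0.53), LEF1 (0.46) and SP5 (0.31) rose, and MYC (−0.34) fell, a call lost with quantile normalization and spike-in scaling. The WNT call was lost with spike-in scaling (adjusted p = 0.078, against a range of 0.0061 to 0.078 over 21 alternatives).

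**Figure D3:**
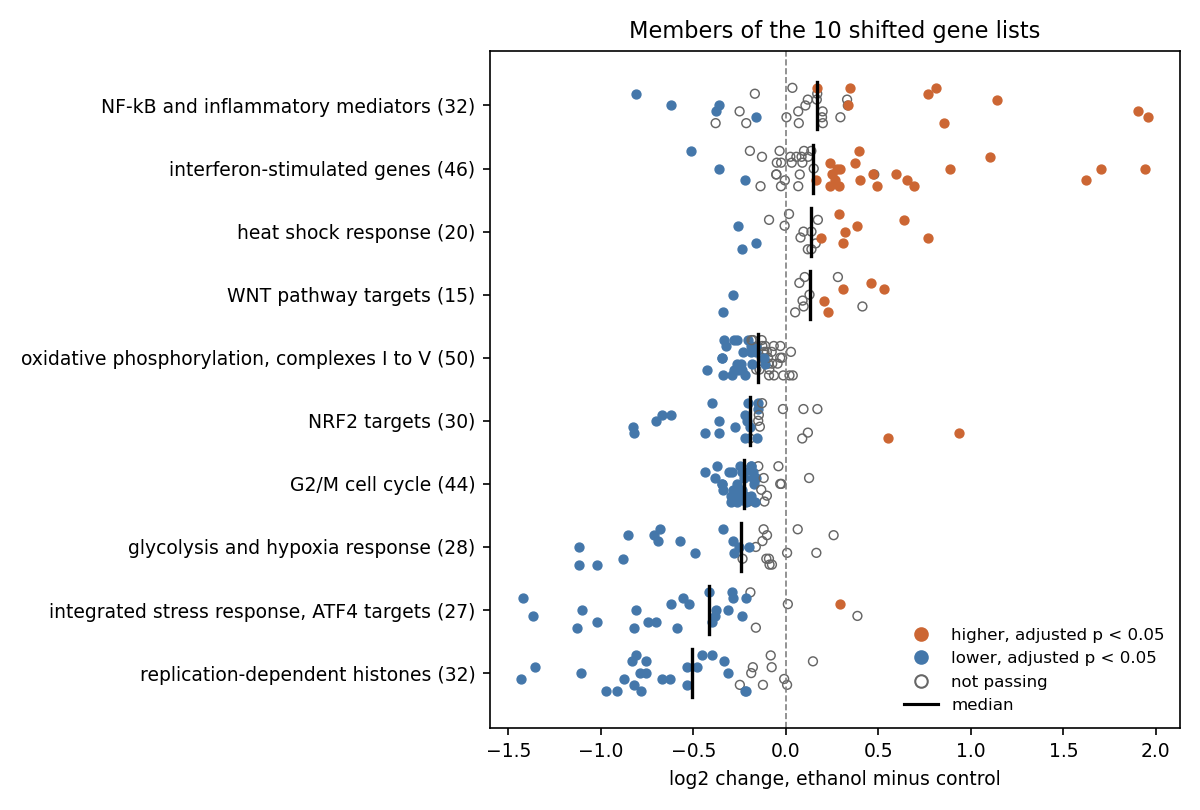
Log2 change, ethanol minus control, of each tested member of the 10 shifted gene lists, with the number of tested members in parentheses. Filled points passed an adjusted p under 0.05, open points did not, and black bars are list medians, from −0.51 for replication-dependent histones to 0.17 for NF-kB and inflammatory mediators.

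Genes of ethanol and acetaldehyde metabolism did not shift as a list (1 higher and 5 lower of 15, also adjusted over the list alone; adjusted p = 0.642), and their median (0.004) and mean (−0.18) differed in sign. ALDH3A1, an aldehyde dehydrogenase abundant in squamous epithelia, fell 3.11-fold (−1.64 ± 0.09), and the alcohol dehydrogenase ADH1C fell 1.53-fold (−0.62 ± 0.09). ALDH3B1 fell by 0.26 on the log2 scale and the acetyl-CoA synthetase ACSS1 rose 1.33-fold. The mitochondrial acetaldehyde dehydrogenase ALDH2 (−0.05 ± 0.05), ALDH1A1 (0.17 ± 0.13), ADH5 (0.03 ± 0.05) and catalase (CAT, −0.03 ± 0.04) did not pass. ADH1B, ADH7 and CYP2E1 were not well above background on any of the 8 arrays. PPARGC1A, a coactivator of mitochondrial biogenesis, had a change of 0.18 ± 0.12 that did not pass.

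Squamous differentiation genes moved in both directions (9 higher and 12 lower of 39, 10 and 12 adjusted over the list alone; adjusted p = 0.97). Their median (−0.05) and mean (−0.05) were below 0, whereas the test against all other genes pointed up. The suprabasal esophageal keratins KRT4 and KRT13 fell 3.04-fold (−1.61 ± 0.10) and 2.13-fold (−1.09 ± 0.11), and SPRR1B fell 1.86-fold. LCE3D and SPRR2E, which encode cornified envelope proteins, rose 1.79-fold and 1.57-fold. Involucrin (IVL) had a change of 0.34 ± 0.14 that did not pass but did under 3 of 21 alternatives. Basal keratinocyte and hemidesmosome genes also went both ways (5 higher and 8 lower of 24, also adjusted over the list alone; median −0.03, adjusted p = 0.962). The basal keratin KRT5 (−0.43 ± 0.04) and DLK2 (−0.59 ± 0.05) fell, while podoplanin (PDPN, 0.72 ± 0.05) rose. The lineage factor SOX2 fell by 0.43 ± 0.07 on the log2 scale, and TP63 (−0.12 ± 0.07) did not pass but did with median scaling. Epithelial junction genes numbered 3 higher and 9 lower of 24, also adjusted over the list alone (median −0.07, adjusted p = 0.295). The splicing factor ESRP1 (−0.39), claudin CLDN1 (−0.42), desmoglein DSG3 (−0.31) and plakophilin PKP3 (−0.26) fell. Genes of the epithelial to mesenchymal transition numbered 7 higher and 6 lower of 26, also adjusted over the list alone (median 0.03, adjusted p = 0.204). The matrix metalloproteinases MMP10, MMP2 and MMP9 rose 2.39-fold, 2.26-fold and 1.94-fold, and N-cadherin (CDH2) 1.41-fold.

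The lipid lists did not pass in the main fit. Cholesterol synthesis and SREBP2 targets had 4 higher and 13 lower of 25 members, also adjusted over the list alone (median −0.18, adjusted p = 0.0999), and passed under 2 of 21 alternatives. INSIG1 fell by 0.50 and SC5D by 0.64 on the log2 scale. Fatty acid synthesis and SREBP1 targets had 7 higher and 3 lower of 18, also adjusted over the list alone (median 0.15, adjusted p = 0.0603), and passed under 3 of 21 alternatives. PNPLA3 (0.52), SREBF1 (0.38), ACSL3 (0.28) and FADS1 (0.21) rose, the calls of ACSL3 and FADS1 being lost with median and spike-in scaling and that of SREBF1 with the mean of its probes (0.17, adjusted p = 0.121). Fatty acid oxidation and PPAR targets had 1 higher and 11 lower of 21, also adjusted over the list alone (median −0.19, adjusted p = 0.0603), and passed under 5 of 21 alternatives. Beside ANGPTL4, the fatty acid binding protein genes FABP4 (−1.05 ± 0.22) and FABP5 (−0.35 ± 0.08) and the dehydrogenase ACADS (−0.55 ± 0.10) fell.

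Chaperones and other unfolded protein response genes had 8 higher and 6 lower of 22 members, also adjusted over the list alone (median 0.11, adjusted p = 0.186), and passed with quantile normalization. DNAJB11 (0.37) and SDF2L1 (0.31) rose, while HERPUD1 (−0.45) and XBP1 (−0.31) fell. HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.17 ± 0.05 on the log2 scale, a call lost under 10 of 21 alternatives, whose adjusted p reached 0.812. Targets of p53 had 4 higher and 7 lower of 27, also adjusted over the list alone (median −0.08, adjusted p = 0.566). TP53I3 (0.56) and SUSD6 (0.31) rose and DDB2 (−0.33) fell, beside GDF15, whereas CDKN1A had a change of −0.15 ± 0.06 that did not pass (adjusted p = 0.106). Fanconi anaemia and homologous recombination genes had 1 higher and 8 lower of 32 (1 and 7 adjusted over the list alone; median −0.05, adjusted p = 0.53). RAD51C (−0.78 ± 0.05), FANCE (−0.40), RAD54L (−0.35) and FANCC (−0.30) fell. One-carbon metabolism and DNA methylation genes had 2 higher and 10 lower of 28, also adjusted over the list alone (median −0.06, adjusted p = 0.212). MTHFD2 (−0.62), AHCY (−0.40) and AHCYL1 (−0.29) fell, and CTH is on this list too. Apoptosis regulators had 5 higher and 8 lower of 33, also adjusted over the list alone (median −0.03, adjusted p = 0.962). The BH3-only gene BMF rose 1.95-fold and the death ligand TNFSF10 1.32-fold, while HRK (−0.58) and BCL2L2 (−0.47) fell.

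Xenobiotic metabolism, AHR target and UDP-glucuronosyltransferase genes had 2 higher and 9 lower of 18, also adjusted over the list alone (median −0.20, adjusted p = 0.16). CYP2S1 (−0.64), ABCG2 (−0.43) and GSTA4 (−0.35) fell and CYP2J2 (0.47) rose. Retinoid metabolism and retinoic acid targets had 2 higher and 6 lower of 21, also adjusted over the list alone (median −0.02, adjusted p = 0.566). TGM2 fell 2.12-fold and CRABP2 1.59-fold, and DHRS3 fell by 0.41 on the log2 scale. Notch pathway genes had 3 higher and 8 lower of 17 (3 and 9 adjusted over the list alone; median −0.15, adjusted p = 0.212), with HEYL (0.75) and LFNG (0.71) higher and NRARP (−0.38) and HES2 (−0.30) lower. Immediate early genes had 5 higher and 9 lower of 28 (7 and 10 adjusted over the list alone; median −0.07, adjusted p = 0.881). EGR3 (0.79) and CCN2 (0.57) rose, and DUSP6 (−0.64) and PHLDA1 (−0.47) fell. Autophagy and lysosome genes had 6 higher and 5 lower of 39, also adjusted over the list alone (median −0.05, adjusted p = 0.993), among them ULK2 (0.65) and UVRAG (−0.31). Proliferation brakes and quiescence genes had 3 higher and 6 lower of 18 (3 and 8 adjusted over the list alone; median −0.16, adjusted p = 0.253). CDKN2D (−0.57), KLF9 (−0.39) and CDKN1B (−0.29) fell and FOXO1 (0.20) rose, a call lost with median and spike-in scaling. Metallothioneins and metal response genes had 0 higher and 1 lower of 12, with none adjusted over the list alone (median −0.03, adjusted p = 0.962). The zinc transporter SLC39A10 (−0.41) fell, a call lost under 4 of 21 alternatives, while MT1F (0.13), MT1M (−0.41) and MTF1 (−0.05) did not pass.

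Ribosomal protein genes had 0 higher and 3 lower of 43 (0 and 1 adjusted over the list alone; median −0.04, adjusted p = 0.63). RPL22 (−0.22) and RPS3 (−0.28) fell, the call of RPS3 being lost under 10 of 21 alternatives and that of RPL22 with quantile normalization and spike-in scaling, and RPL3 (−0.26) did not pass but did under 9 of 21 alternatives. Without ethanol replicate 1, whose array stands apart from the other ethanol arrays, the ribosomal list shifted lower (median −0.18, adjusted p = 0.00125, against 0.00125 to 0.938 over 21 alternatives), as it did with array weights. These calls rest on the preset correlation of 0.01. The correlation estimated for this list in the main fit was 0.83 (camera adjusted p = 0.898 with it), so the preset is low for these genes. Of the markers of other cell types, fibroblast genes had 3 higher and 2 lower of 7, also adjusted over the list alone. Their median (0.02) and mean (−0.07) differed in sign (adjusted p = 0.53). FAP (0.67) and COL5A1 (0.33) rose while DCN (−1.19) and S100A4 (−0.42) fell. Immune cell markers had 2 higher and 1 lower of 9, also adjusted over the list alone, with a median of −0.04 and a mean of 0.01 (adjusted p = 0.566). CSF1R (0.74) and CD68 (0.22) rose, the call of CD68 being lost with median and spike-in scaling, TYROBP (−0.43) fell, a call lost under 10 of 21 alternatives, and CD3D (−0.25) did not pass. Columnar and intestinal epithelium markers had 0 higher and 2 lower of 10, also adjusted over the list alone (median −0.19, adjusted p = 0.204; adjusted p = 0.0381 without ethanol replicate 1). KRT19 (−0.54) and KRT8 (−0.19) fell, the call of KRT8 being lost with quantile normalization, spike-in scaling and the mean of its probes, whereas MUC2 (−0.27) and CDX1 (−0.19) did not pass but did under 4 and 3 of 21 alternatives. Only 4 endothelial markers were tested, too few for a list test. VWF fell by 0.27 ± 0.08 on the log2 scale, a call lost under 11 of 21 alternatives and turned to 0.048 (adjusted p = 0.783) with the mean of its probes, and CDH5 (−0.03), TEK (0.02) and ESAM (0.38) did not pass.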

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

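The test of slide rows and the test of a GC trend as the whole cause were chosen after the results were seen. The other tests of this part were set before their results were seen.

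In 22 of 334 sets of 4 arrays from 167 named genes that were tested (6.59%), a single array lay far from the other 3 of its group, as measured by its gap over the group's range. Chance gives about 5% of such sets. Among the control arrays these gaps were 0.839 of the range for ATP5MC1, 0.898 for BCL2L2, 0.836 for CDKN1B, 0.890 for CFAP100-DT, 0.8996 for DUSP6, 0.913 for ESRP1 and 0.8291 for HMOX1. They were 0.869 for HSPA5, 0.842 for IVL, 0.849 for MTHFD2, 0.883 for MYC, 0.869 for NDUFS7, 0.843 for RPL3 and 0.922 for TP53I3. Among the ethanol arrays they were 0.872 for CYP2J2, 0.851 for DDIT3, 0.874 for FABP5, 0.859 for LEF1, 0.856 for MMP10, 0.956 for NQO1, 0.839 for SPRR1B and 0.847 for TP53I3. Outside the named genes of the comparison, 522 probes without a gene symbol were higher and 576 lower with ethanol, of 6248 tested.

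Changes in 6187 genes between 2 groups of 4 arrays were weighed first. Among genes without missing values the real grouping gave 6180 changed genes, and 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many. The highest of the other splits gave 0 by limma, and up to 2515 genes at an unadjusted p under 0.05 against 7631 for the real grouping. The other splits mix ethanol and control arrays, which widens the spread within their groups and lowers their counts. With 35 splits the real one can at best be 1 of 35, so chance is argued against but not excluded. A trend with probe GC content or with brightness is argued against as the whole cause, since 6268 genes changed after the GC trend was removed (95.4% of the original calls kept) and 5721 after cyclic loess normalization (82.7% kept). Ethanol itself and the row of the slide cannot be told apart, because 0 slide rows held both groups, and both stay open.

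Ethanol replicate 1 stood apart from the other ethanol arrays, with correlations of 0.994 to 0.995 to them against 0.996 to 0.997 among the other 3, and it was the farthest array in 62.4% of the 925 genes with a far ethanol array. Its lower overall signal (934 units) is argued against as the cause, because its deviation also exceeded the others in the brightest 25% of genes (SD ratio 1.69 ± 0.02, bootstrap SE over genes). A larger response to ethanol predicts that the difference of ethanol replicate 1 from replicate 4 correlates positively with the effect in replicates 2 and 3. The correlation was −0.14. Opposite trends of these arrays with probe GC content could lower it, and it was not repeated without them, so this explanation stays open. The deviation of ethanol replicate 1 correlated at 0.25 with probe GC content, and that of ethanol replicate 3 at −0.25. Each array was set against the mean of the other 3, so a trend in 1 array pushes the others the opposite way. These 2 correlations are thus not independent. With the GC trend removed, the SD ratio of replicate 1 was still 1.66 ± 0.03. A contribution of GC content stays open, as does a difference between the cultures or their RNA, which was not tested.

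Lower expression of ATF4 targets and of glycolysis and hypoxia genes may reflect sparser cultures with ethanol, in which medium and oxygen last longer. The YAP target signature, known to rise at low density, had a median of 0.000136 over 21 members (3 higher, 8 lower; limma camera adjusted p = 0.602), and members that go both ways decide nothing. A trend with probe GC content is argued against, since the median over the 55 tested members of both lists was −0.34 before and −0.35 after its removal. Cell density and a direct effect of ethanol stay open, as does the slide row.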

How the results depend on the processing

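Over all alternatives, spike-in scaling aside, between 4855 and 7119 genes changed, against 6187. Scaling on spike-ins, added after the data were seen, gave 2470 changed genes and 701 lower ones. Its spike-in level relative to the 75th percentile varied from 1.91 to 2.31 (log2) among the control arrays alone, which adds spread to every gene. Median scaling gave 1251 higher genes, with all genes shifted down by its construction. Normexp with an offset of 50, which compresses dim probes, gave 545 genes changed at least 1.5-fold. The mean of a gene's probes turned VWF to 0.048 (adjusted p = 0.783), and the cause was not tested. Leaving out each replicate in turn gave 5044 to 6550 changed genes, 2086 to 2598 higher, 2958 to 3952 lower, 997 to 1125 changed at least 1.5-fold and 10 to 12 shifted lists. The highest count came without ethanol replicate 1. No other count of genes or lists moved by over 1.5 times. Of the 6187 calls, 5710 were shared with the deposited table, 5637 with the arrays without ethanol replicate 1 and 5903 after removal of the GC trend, also added later (6268 changed). The 10 shifted lists kept the call in 209 of 210 comparisons with an alternative, WNT targets with spike-in scaling being the exception. The other 25 lists stayed without a call in 511 of 525 comparisons and gained one in 14. Of 3098 comparisons of the 148 named genes that changed, 2980 kept the call, 117 lost it (53 of them with spike-in scaling) and 1 turned. The 19 named genes that did not pass stayed so in 376 of 396 comparisons and gained a call in 20. Control and ethanol arrays of the same replicate number deviated together with correlations over genes of 0.24, 0.07, 0.12 and 0.17, all positive, though not every array correlated best with its own number. The replicate number was also the slide column on every array, so paired cultures and a shared position cannot be told apart. The main fit kept group as its single term, as fixed beforehand, and did not take the numbers as pairs. With the replicate number as a block, 5889 genes changed (5405 shared), 2380 higher and 3509 lower, 1072 of them at least 1.5-fold, and 12 lists shifted, the 2 fatty acid lists among them. The planned fit with the slide as a term was not run because all arrays lay on 1 slide. Signal over background limits the dim genes, since 55.1% to 60.4% of probes were well above background.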

Other observations

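All tests of gene families, and those of S phase and of neighbouring genes without histones, were chosen after the results were seen. The families were formed from the letters with which gene symbols start, and 206 of them with at least 10 members were tested by camera at the preset correlation. Of these, 9 passed, and none did with an estimated correlation, where the smallest adjusted p = 0.626. Transcripts that host small nucleolar RNAs (SNHG) fell in 13 of 20 members and rose in none (median −0.41, adjusted p = 9.32e-05), with SNHG32 at −0.89, SNHG10 at −0.84 and SNHG5 at −0.73. Symbols of aldo-keto reductases (AKR) fell in 8 of 12 members and rose in none (median −0.53, adjusted p = 0.00183). AKR1C4 (−0.89), AKR1B15 (−0.86) and AKR1B10 (−0.83) fell most, 3 of the 12 are also on the NRF2 list, and their similar sequences can share probes.

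Symbols of mitochondrial ribosomes fell in small steps, 28 of 52 for the large subunit (MRPL, median −0.15, adjusted p = 0.00183) and 16 of 29 for the small one (MRPS, median −0.14, adjusted p = 0.0183), with none higher. The MRPL symbols include antisense transcripts, of which MRPL20-AS1 (−0.22) is among those that fell, and a pseudogene. With spike-in scaling these medians were −0.04 and −0.03 and the shifts did not pass (adjusted p = 0.232 and 0.365). Coenzyme Q synthesis genes (COQ) fell in 7 of 11 members and rose in none (median −0.26, adjusted p = 0.0261), and did not pass without ethanol replicate 1 (adjusted p = 0.081) or with spike-in scaling (0.16). Symbols of matrix metalloproteinases (MMP) rose in 9 of 17 members and fell in 2, MMP28 (−0.49) and the opposite-strand transcript MMP24OS (−0.36) (median 0.43, adjusted p = 0.0183), 5 of them on fixed lists, with MMP3 at 1.16 and MMP24 at 1.04 beside MMP2 and MMP10. Symbols of interleukins and their receptors (IL) were higher in 19 and lower in 9 of 60 (median 0.15, adjusted p = 0.0183), among them IL20 (1.32) and IL32 (1.13), and they include the divergent transcripts IL6ST-DT (0.40) and IL10RB-DT (−0.54). Symbols of golgins (GOLGA) were higher in 10 and lower in 3 of 22 (median 0.35, adjusted p = 0.0183), mostly near-identical copies that can share probes, with pseudogenes among them. ADAM symbols were higher in 7 and lower in 2 of 17 (median 0.11, adjusted p = 0.0372), and did not pass without ethanol replicate 1 (adjusted p = 0.103). The medians of these 9 families kept their sign with median and with spike-in scaling, but with median scaling that of ADAM was 0.006 and that of IL 0.05, and with spike-in scaling that of COQ was −0.15.

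ABCA1 and ABCG1 are textbook targets of the oxysterol receptor LXR, and a general rise of LXR targets is a candidate explanation of their increase. The other 13 tested LXR targets had a median of 0.042 (4 higher, 4 lower; limma camera adjusted p = 0.602), with MYLIP (0.79), SMPDL3A (0.40) and SREBF1 (0.38) higher and APOE (−0.49) lower. Members that go both ways leave the hypothesis open.

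Fewer cells in S phase could lower replication-dependent histones. The G1/S list had a median of −0.064 against −0.51 for the histones, short of the fall that the prediction for this explanation asked for. Its members go both ways (4 higher, 11 lower), which leaves this open. Probe sharing among histones and the small tailed fraction of their transcripts were not tested.

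If the ethanol and control cultures were different subclones, copy number differences could shift neighbouring genes together. Among 15056 runs of 50 neighbouring tested genes, the farthest from the median of all genes lay on chromosome 6, at −0.32, past the bound of 0.3 set before the result was seen. That run held 18 listed histones (median −0.69) and 32 other genes (median −0.22), of which 13 were further histone symbols. With the listed histones left out, the largest shift of any run was 0.18, which argues against this explanation for the remaining genes at this run length. On chromosome 6 the largest shift was then −0.10, so no run of 50 neighbouring genes there lay past the bound. For the chromosome 6 run, a narrower copy number difference and a shared regulation of histones both stay open.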
